A study of Rattus norvegicus with 448 samples.

How the data were processed

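Liver RNA of outbred rats aged 17 weeks was sequenced, per the labels, as 37 bp paired-end reads on an Illumina HiSeq instrument after Trizol extraction of snap-frozen tissue. The labels list 448 liver libraries, all in the same group, with no sex, treatment, genotype or batch. Of these, 430 carry an identifier shared with adipose tissue samples, made of a first and a second part joined by a low line. The deposited table names its columns by that identifier and holds 16796 genes. Each of the 430 libraries with an identifier was matched to its own column, and the other 18 libraries are not analysed here. There was 1 further column of values whose identifier matched no library in the labels, and it was not used.

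STAR, Picard, featureCounts and DESeq2 are named in the submitters' processing notes, without versions or roles. The genome build, the annotation and the strand setting are not given in the sources used here. The table has no unit in its header. The deposited values are FPKM, fragments per kilobase of gene scaled by library, as read from the values themselves: within a library and a gene they are whole multiples of a fixed step. After the steps were recovered, 99.84% of all values were whole reads within a tolerance of 0.001. The product of a library's step and its median-ratio size factor was constant over libraries (coefficient of variation 0.0002), and the product of step and recovered reads was not (0.094). The deposited values thus follow a scaling by a median-ratio size factor and not by the total, and FPKM totals ranged from 430947 to 1273438 among libraries. Because the recovered reads depend on the recovered steps, a depth given here is a reconstruction and not a deposited count.

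Gene IDs were used as the table gives them. The sources used here do not pair these IDs with gene names: 0 of the 16796 IDs occurred in the gene name table that was used. For this reason the tests fixed in advance on pathway lists and cell type marker lists, and the correlations between such lists, could not be run, and the rule for naming genes, which required a gene symbol, named none. The few IDs printed below were chosen after their values were seen, as the extreme gene of a ranking. A comparison of libraries without an identifier to those with one was also fixed in advance and was not run, since the former had no column.

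All tests used log2(FPKM + 1) of the 12234 genes at 1.0 FPKM or more in at least 10% of the libraries, so a fold change of a gene near 1 FPKM is understated. The spread of a gene was its SD over libraries, and its excess SD the difference to a lowess curve of SD on mean level. Bimodal genes were called by a mixture of 2 normal components with a common variance: means at least 4 SDs apart, at least 5% of libraries in the smaller component, a gain in the Bayesian information criterion above 10, and an upper mean at or above the 25th percentile of level. Resemblance among libraries that share the first part of the identifier was tested per gene with limma's moderated F test with a variance trend, with a natural spline of the title number (4 degrees of freedom) as covariate. Its size was the intraclass correlation (ICC), the share of variance that lies between identifiers. A linear trend over the title number was tested per gene with limma. Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05. The labels do not say what the first part of the identifier means, nor that each library is a separate animal. The p-values of the F test set the spread between identifiers against that within them. Those of the trend rest on the spread of libraries around the fitted line. Both take libraries as independent, which neighbouring libraries were not.

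Neighbouring pairs were libraries with different first parts and title numbers at most 6 apart. The resemblance test was repeated on 99 sets of groups of the same sizes, drawn from neighbouring libraries with different identifiers, and the trend test on 99 shifts of the title numbers round the ring of libraries. Intervals for pairs came from 1000 bootstrap draws over identifiers. The alternatives fixed before the data were examined were pseudocounts of 5 and 0.5, no filter, a filter at 10 FPKM, an upper quartile rescaling, leaving out the 5% of libraries with the fewest genes detected (22 libraries), other bounds for bimodal genes, normal scores, no spline, Spearman's correlation, and the first 5 principal components as covariates of the resemblance test. Chosen after the data were seen were limma-voom on the recovered reads, the removal of components or their use as covariates in the other results, the resemblance test with the first 5 components and without those 22 libraries together, and the first component's share of variance with its alternatives.

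Each step was tested on simulated reads with the real gene levels, library steps and 12234 genes. For the trend, 94 of 100 genes with a simulated slope of 0.1 and 99 of 100 with 0.2 (log2 per 100 title numbers) were called, with 9 calls among 11634 genes made without any effect. For the resemblance, 15 of 100 genes with an ICC of 0.3 and 71 of 100 with 0.5 were called, with 7 calls among the 11634. For bimodal genes, 68 of 100 with a gap of 2.0 and 69 of 100 with a gap of 3.0 (log2) were called, with 0 calls among the 11634. The simulated smaller mode was the lower one and held more of the libraries than that of most real bimodal genes. Before counting noise, the simulated modes also lay farther apart than the real median of 4.39 SDs. The 68 and 69 therefore do not give the share of real bimodal genes that is found. In the real data the count of bimodal genes fell from 492 to 98 without the libraries with the fewest genes detected. It fell to 56 after removal of components. The 0 calls among simulated genes therefore give no rate of false calls for the real data. For the trend and the resemblance, the simulated spread of a gene was taken after removal of components, which the main tests keep. Without the first component alone, the real median SD was 0.274, against 0.377 with it. The calls among simulated genes thus hold for a smaller spread and give no rates for the main tests. The simulated libraries were also independent of each other, which the real ones were not. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and in R 4.3.3 with limma 3.58.1.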

Results

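Gene expression was measured in 430 liver libraries of outbred rats aged 17 weeks, a population in which the study mapped loci for metabolic traits and the liver genes whose expression has a genetic influence nearby. Recovered reads per library had a median of 36729739, with quartiles of 29845125 and 42432472 and a range from 146208 to 88571385. There were 13 libraries under 10000000 reads, of which 2 lay under 1000000. A library had 7108 to 16613 genes above 0, with a median of 15877. The 10 genes with the highest mean level took 9.38% ± 1.64 (SD, n = 430) of the FPKM of a library and the top 100 took 33.6% ± 2.6. Among the 10 pairs of libraries most alike in centred log2 levels, none differed by counting noise alone. The most alike, LSW_389 and LSW_391, had a correlation of 0.917. Their recovered reads differed by a chi-square of 13.5 per degree of freedom. That pair shared the first part of the identifier. The other pairs did not, and had 29.9 to 57.2. All 10 were made of libraries with reads below the lower quartile. Further pairs were not tested, so a library present more than once is not excluded. The chi-square covers counting noise only, so a second preparation of a sample is not excluded either.

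Most liver genes varied little between libraries, and a small number varied widely. The SD over the 430 libraries had a median of 0.377 on the log2(FPKM + 1) scale over 12234 genes, with quartiles of 0.288 and 0.522 and a range from 0.125 to 2.909. There were 1683 genes with an SD under 0.25 and 215 with an SD of at least 1. Relative to genes of the same mean level, 410 genes had an excess SD of at least 0.5, and the highest excess was 2.504. Counting noise of the recovered reads accounted for a median of 4.7% of a gene's variance and for 22.6% at the 95th percentile of genes. The median SD depended on the pseudocount: it was 0.232 with 5 and 0.433 with 0.5.

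A large block of genes moved together. The first principal component held 45.7% of the variance over libraries, and the next 4 held 4.7%, 3.8%, 2.8% and 2.2%. Of the 12234 genes, 1887 had a correlation above 0.8 with the component and 1012 a correlation below -0.8. The first set had a median level of 2.64 and the second a median level of 5.55 (log2), against 2.97 for the genes tested. The score rose with log10 recovered reads (Pearson r = 0.582, Spearman rho = 0.531, adjusted p = 1.3e-05 for each, permutation tests with 100000 resamples, two-sided). It rose also with the number of genes above 0 (r = 0.641, rho = 0.685) and fell with the share of the top 100 genes (r = -0.341, rho = -0.343), each at the same adjusted p, from the smallest p that the permutations can give. For each measure, the 2 libraries farthest from its own median were also left out, and these r were then 0.675, 0.757 and -0.379. In 4 consecutive blocks of libraries by title number, r with log10 reads was 0.548, 0.558, 0.655 and 0.722. Over those blocks r with genes above 0 was 0.632, 0.618, 0.726 and 0.781, and r with the share of the top 100 genes was -0.225, -0.378, -0.342 and -0.454. The number of genes above 0 and the share of the top 100 genes come from the same values as the score. Part of their relation to the score can thus be built in. The permutations take libraries as independent, which neighbouring libraries were not, so the p-values may be too small. No relation to the title number was found (r = -0.034, rho = -0.009, adjusted p = 0.48 and 0.85, permutation tests, 4 relations in the family), although r was 0.188, -0.403, 0.073 and 0.053 in the blocks. Without the 2 libraries whose title numbers lay farthest from their median, r was -0.043, which is no check on outlying scores. Without the first component the median SD fell from 0.377 to 0.274.

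**Figure D1:**
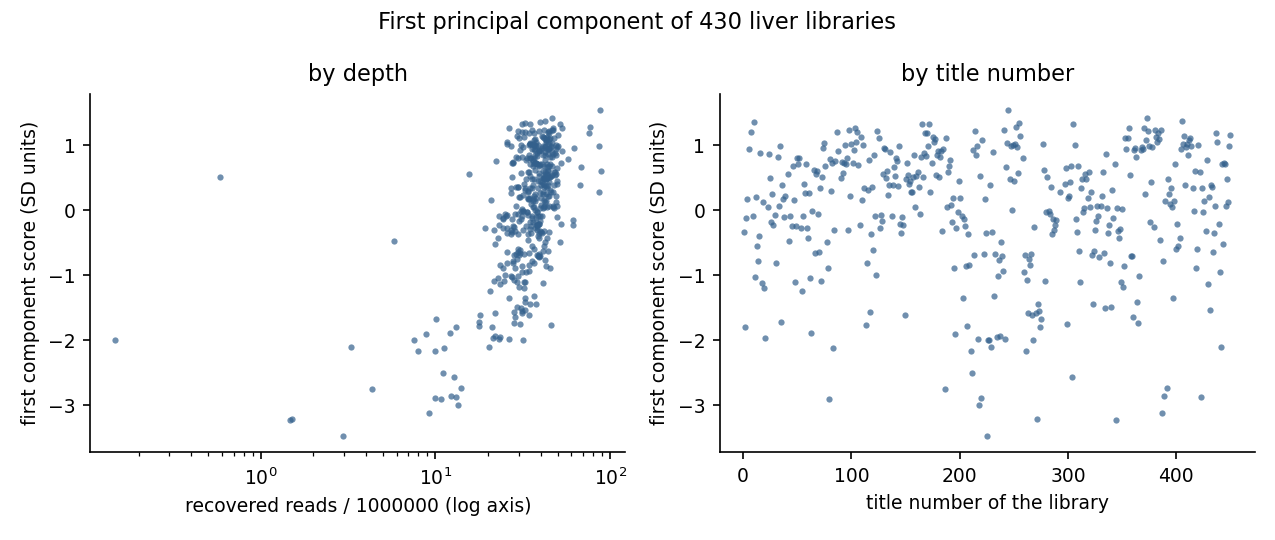
Score of the first principal component in each of the 430 liver libraries, in SD units, against recovered reads (scaled by 1000000) on a log axis (left) and against the title number (right), 1 point per library. Libraries with fewer reads had lower scores (r = 0.582 with log10 reads), while the score had r = -0.034 with the title number.

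The number of bimodal genes depended on the bounds for calling them, and ranged from 50 to 1943 over the alternative bounds. At the bounds set here, the level of 492 genes fell into separate classes of libraries. Their modes lay a median of 1.83 apart (log2), and the smaller mode held a median of 27 libraries. In 440 of the 492 the smaller mode held under 10% of the libraries. It was the lower mode in 255 genes and the upper one in 237. Without the 22 libraries with the fewest genes detected, 98 genes were called, 84 of them among the 492. After removal of the first 5 components, 56 genes were called, 43 of them among the 492. There were 42 genes called in all 3 settings, and they are called the retained genes here.

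The modes of the retained genes lay a median of 1.99 apart on the log2(FPKM + 1) scale, with a range from 1.1 to 4.57, and the smaller mode held a median of 100.5 libraries, with a range from 23 to 214. In 21 of the 42 the lower mean lay under 1 FPKM. The retained gene whose modes lay farthest apart in units of their common SD, ENSRNOG00000013238, had 2.82 ± 1.15 FPKM (SD) in the 80 libraries of its upper mode and 0.14 ± 0.12 FPKM in the 350 of its lower mode, a distance of 8.07 common SDs and a gap of 1.69 (log2). ENSRNOG00000020006, the retained gene with the highest ICC, had 2.6 ± 1.01 FPKM in 85 libraries and 0.64 ± 0.24 FPKM in 345, a distance of 4.5 SDs. Classes were defined from the levels themselves, so the gap between them is a description and carries no p-value. Of the other 450 bimodal genes, 433 had under 10% of the libraries in the smaller mode. The 22 libraries with the fewest genes detected held 59.5% of the smaller-mode calls of these 450 genes. For the retained genes that share was 6.2%, but those genes were kept for being called without the 22 libraries.

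**Figure D2:**
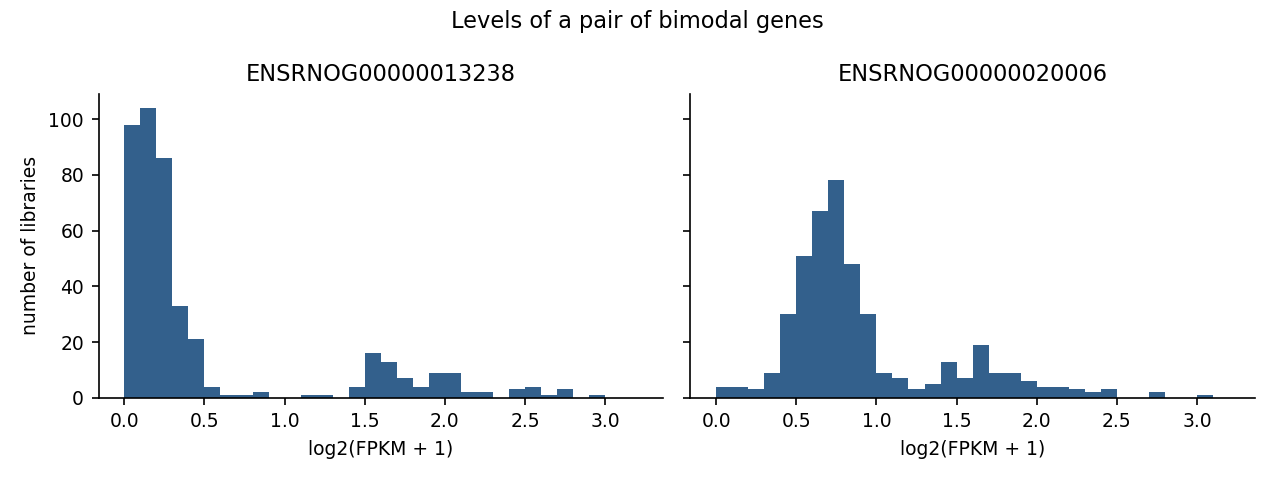
Number of libraries by log2(FPKM + 1) for 2 bimodal genes in 430 liver libraries, in bins of equal width. The upper class held 80 libraries for ENSRNOG00000013238 and 85 for ENSRNOG00000020006.

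Libraries that shared the first part of the identifier resembled each other in the expression of many genes. There were 92 such identifiers, 83 shared by 2 libraries and 9 by 3, which gave 193 libraries and 110 pairs. In the moderated F test of limma, 6686 of the 12234 genes differed between identifiers at an adjusted p under 0.05. The count was 10498 on normal scores, which were fitted without the variance trend, and 3217 without the 22 libraries with the fewest genes detected. The higher count on normal scores did not come with a higher ICC. Its median there was 0.197, and 174 genes reached 0.5, against 0.199 and 202 genes in the main fit. The ICC had a median of 0.199 over all genes tested, with quartiles of 0.129 and 0.277, and a median of 0.269 over the genes past the threshold. It was at least 0.5 in 202 genes, of which 34 were bimodal, and reached 0.76 in ENSRNOG00000020006 (adjusted p = 8.84e-17). For ENSRNOG00000013238 the ICC was 0.7 (adjusted p = 1.09e-13).

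Sharing libraries also lay close in title number, with a median gap of 3, and neighbouring libraries with different identifiers resembled each other too. Over genes tested, the median correlation was 0.194 for sharing pairs, 0.124 for neighbouring pairs with different identifiers and -0.01 for distant pairs. Groups drawn from neighbouring libraries with different identifiers gave a median of 286 genes over 99 draws, and at most 6828. The next highest draws gave 6489, 5737 and 5663 genes, so the highest did not stand alone. The median ICC in these draws was 0.112 at the middle and 0.212 at the highest, so the 0.199 of the real groups was within reach of neighbours. With the first 5 components as covariates, 6868 genes differed between shared identifiers, 5075 of them among the 6686, and the draws then gave a median of 549 and at most 1694 genes. The median ICC was 0.212 in that fit and at most 0.104 in its draws. An ICC of at least 0.5 was reached by 376 genes in that fit and by at most 53 in the draws. Without the 22 libraries with the fewest genes detected, 173 libraries remained and 3217 genes were called, 3065 of them among the 6686, and the median ICC fell to 0.131. With those libraries left out and the 5 components as covariates, 7880 genes were called, with a median ICC of 0.249.

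**Figure D3:**
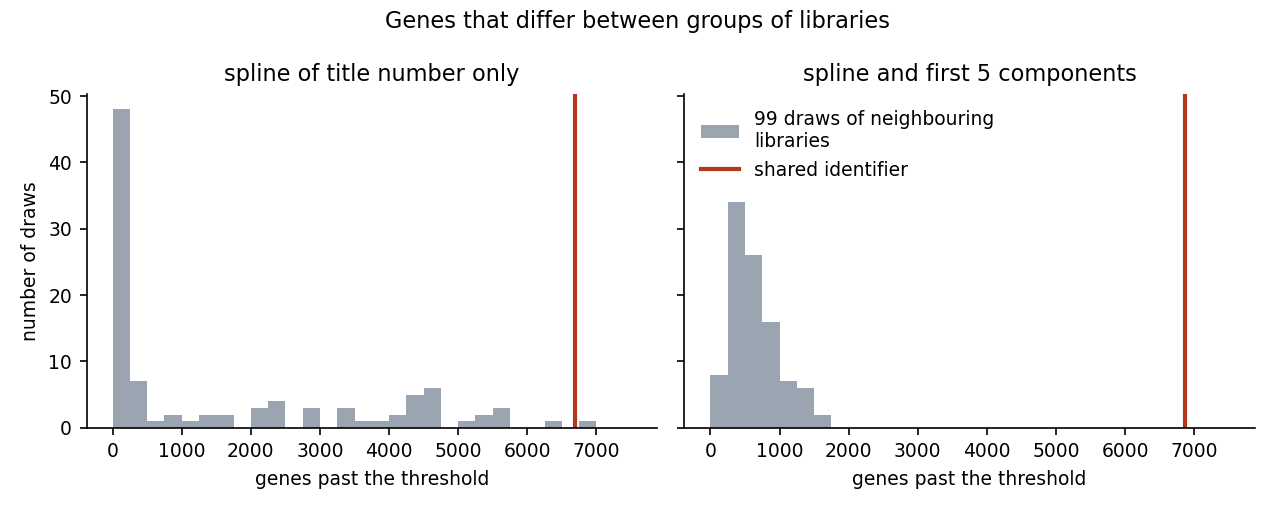
Number of genes past an adjusted p of 0.05 in 99 draws of groups of neighbouring libraries with different identifiers (grey bars) and for the groups that share an identifier (red line). With the spline of the title number alone, the line stood at 6686 and the highest draw at 6828. With the first 5 components as further covariates, the line stood at 6868 and the highest draw at 1694.

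Among the retained genes, the F test over identifiers passed the threshold in 41 of 42, and their ICC had a median of 0.542, with a range from 0.097 to 0.76. For the other 450 bimodal genes the median was 0.244, and 390 passed. Sharing pairs had the same mode in 83.3% of pairs and genes (54.8% to 97.6% of the genes in single pairs), against 66.0% for neighbouring pairs with different identifiers and 66.0% for distant pairs. The correlation of modes had a median of 0.483 over the 42 genes for sharing pairs (95% bootstrap interval over identifiers 0.417 to 0.539) and of -0.004 for neighbouring pairs (-0.021 to 0.01). In 42 of the 42 genes it was higher for sharing pairs.

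**Figure D4:**
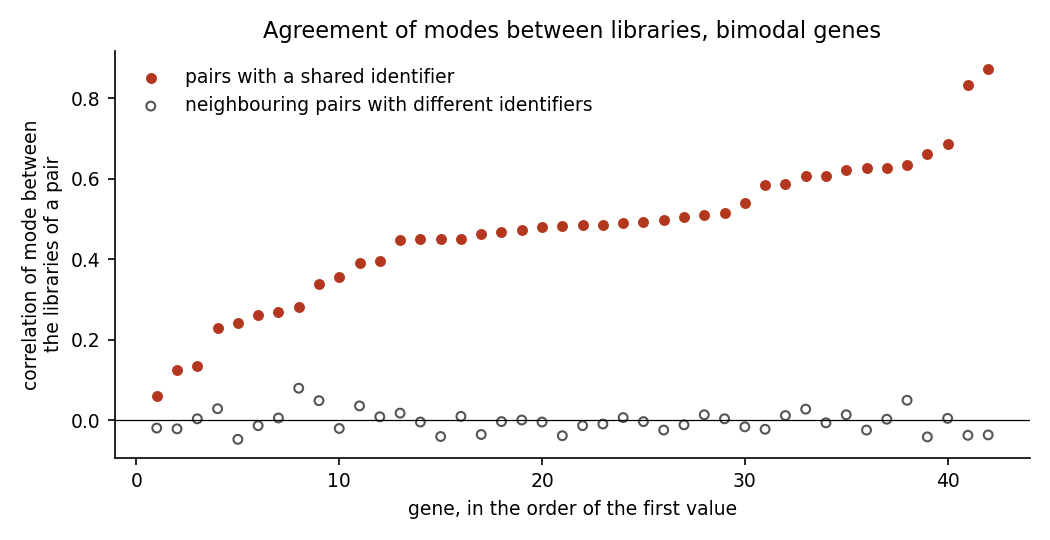
Correlation of the mode between the libraries of a pair for each of the 42 retained genes, for pairs with a shared identifier (filled points) and neighbouring pairs with different identifiers (open points). Values ranged from 0.061 to 0.872 for sharing pairs and from -0.047 to 0.08 for neighbouring pairs.

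Over the title number, 525 genes rose and 476 fell in the linear test of limma, 1001 genes in all. The slopes of these genes had a median size of 0.048 (log2 per 100 title numbers). The steepest rise was that of ENSRNOG00000029145, by 0.21 per 100 title numbers (SE 0.0438, adjusted p = 0.000212, n = 430), and the steepest fall that of ENSRNOG00000021027, which fell by 0.45 (SE 0.0443, adjusted p = 8.47e-18). The count of 1001 genes did not stand out from shifted orders of the libraries: 99 shifts of the title numbers gave a median of 1504 genes and at most 8675. With the first 5 components as covariates 3079 genes were called, and the shifts gave a median of 2074 and at most 3705. Neighbouring libraries were alike, so the adjusted p-values of this test, which take libraries as independent, were too small.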

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

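The median SD of 0.377 stayed within its bootstrap SD of 0.0133 in 2 of 7 alternatives. It was 0.232 with a pseudocount of 5, 0.433 with 0.5, 0.316 without a filter, 0.322 without the 22 libraries with the fewest genes and 0.274 without the first component. The first component's share of 45.7% (bootstrap SD 2.24) became 49.1% with a pseudocount of 5, 51.1% at 10 FPKM and 43.3% without the 22 libraries, and lay between 43.8% and 45.4% in the other 3 alternatives. The 492 bimodal genes became 1943 at a distance of 3 SDs, 78 at 5 SDs, 1441 with 2% and 50 with 10% of libraries in the smaller mode, 316 at 10 FPKM, 98 without the 22 libraries and 56 without 5 components. In the other 4 alternatives they numbered 467 to 595, though of the 514 called with a pseudocount of 5 just 299 were among the 492, against 390 of 467 with 0.5 and 389 of 483 with upper quartile rescaling. The 6686 genes with resemblance became 3898 at 10 FPKM, where 6175 genes were tested, 3217 without the 22 libraries and 10498 with normal scores, and lay between 6559 and 8280 in the other 8. The 1001 genes with a trend became 592 at 10 FPKM, 1528 without the 22 libraries, 1548 with Spearman's correlation and 3079 with 5 components, and lay between 943 and 1331 in the other 5. Fewer genes tested lower the counts at 10 FPKM, and the bounds set the counts of bimodal genes by construction. For the other changes the cause was not tested. The trend in libraries with an identifier was not run apart, since every library used has 1. The alternatives for the gene lists and for libraries without an identifier were not run either. At the depth of the 13 libraries under 10000000 reads, low-level genes were often at 0, which limits what their levels can show.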

Other observations

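The tests of the first component against depth, title number and identifier, the tests on the 42 retained genes, the ratio of neighbouring to sharing correlations and both tests with components as covariates were chosen after the results were seen, and the others before.

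Among the 42 retained bimodal genes, most pairs of genes were weakly correlated over libraries: the median size of r over the 861 pairs was 0.063. There were 4 pairs at 0.5 or more and 4 at -0.5 or less. The most strongly linked pair had an r of 0.935, the next 0.81, and the most opposed pair -0.744. In the wider set of 492 bimodal genes, 19633 pairs had an r of 0.8 or more and 15347 an r of -0.8 or less, so 43.9% of linked pairs were negative. That share was meant to test whether reads moved between near-identical gene copies may link genes in opposite directions. It cannot decide this, because the 492 genes had a median size of r of 0.829 with the first component, which sets both signs, and only 2 pairs of retained genes reached 0.8 in size.

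The first component held 45.7% of the variance. The 249 libraries within 20% of the median number of reads had a first component of their own that held 39.2%. A large component was thus found at similar depth. Its genes were not compared with those of the component over all libraries, whose score rose with reads. What part depth has in the component over all libraries is therefore not settled. Position in the series as the whole source is argued against, since runs of 10 consecutive libraries held 0.154 of the variance of the scores. Scores of neighbouring pairs had a correlation of 0.196, so position goes with part of the first component. For the identifier, the correlation of scores over sharing pairs, 0.201, exceeded that over neighbouring pairs by 0.005 (95% bootstrap interval -0.248 to 0.282), which decides nothing. Across genes, which are not independent replicates, the loading had a Spearman correlation of 0.437 with the recovered gene length. That length was inferred from the step of each gene and not read from an annotation. A candidate explanation is a difference between libraries in how well long transcripts were kept or captured, as RNA quality could give. The component also went with level: the median was 2.6 (log2) for genes with r above 0.8 and 5.5 for those below -0.8. Level was not adjusted for, so the correlation does not separate length from level. No biological explanation was tested.

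Over all 492 bimodal genes, the median size of the Spearman correlation between mode and recovered reads was 0.364, and that of the correlation between mode and the first component 0.592, so most of these genes may be bimodal through the libraries that lie at the end of the first component. For the whole set the excess of sharing over neighbouring pairs in the correlation of modes, 0.21, had a 95% interval of -0.08 to 0.615. For the 42 retained genes these measures cannot weigh depth or the first component, since the genes were kept for being called without the libraries with the fewest genes and after removal of components, which would lower both. If libraries that share an identifier came from an animal sequenced more than once, their modes should be the same in nearly all cases, yet 83.3% were, which argues against this as the general case. Single pairs ranged from 54.8% to 97.6%, so it stays open for the pairs at the upper end. The median correlation of modes of 0.483 (0.417 to 0.539) over sharing pairs is compatible with litter mates that carry inherited expression differences of large effect. Single genes ranged from 0.061 to 0.872, so the median does not describe each gene. ENSRNOG00000013238 and ENSRNOG00000020006, at 0.833 and 0.872, lay well above the interval of the median, and the lowest gene lay well below it. Whether litter mates alone could give such values in single genes was not tested. The labels do not state litters, and litter mates remain a hypothesis without genotypes. A shared cage or diet and reads lost over variants against the reference were not tested.

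The resemblance of libraries with a shared identifier was set against that of neighbours. Of 100 sets of groups, the real one included, 2 gave as many as 6686 genes, the other with 6828, so a draw of neighbours reached the real count, though under 5% of the draws did. With the first 5 components as covariates, 1 of the 100 sets, the real one, reached 6868, and the highest other had 1694. The components as the whole source are argued against, since 75.9% of the genes were called again with them as covariates. Over the 6686 genes, the median correlation of neighbouring pairs was 0.476 of that of sharing pairs (0.123 against 0.258), but these genes were chosen for the resemblance of sharing libraries, and over all genes tested the ratio was 0.637 (0.124 against 0.194), so how much of the resemblance nearness in the series may account for stays open. A common litter, cage or processing day of sharing libraries remains open too.

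The trend over the title number was reached or exceeded in 75 of 100 orders, the real one included, and the highest other gave 8675 genes against 1001. With the first 5 components as covariates, 9 of 100 orders gave as many as 3079 genes, and the highest other gave 3705. Runs of alike neighbours could therefore give a trend of this extent in either fit.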
